A study of Homo sapiens with 3 samples.

How the data were processed

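Strand-specific poly-A libraries of KKU-213 at 5.6 mM glucose (NG), KKU-213 at 25 mM glucose (HG) and KKU-213L5 at 25 mM glucose (L5) were sequenced as paired reads of 100 bp, per the labels, with 1 library per group. The FPKM values were made by the authors with BWA, TopHat and Cufflinks on GRCh37 and are used as deposited; no versions were stated. The coverage values are the mean read depth per transcript that Cufflinks writes, per the file headers, not normalized for library size. The bounds of the FPKM interval were also used as deposited; the interval held the listed FPKM for 86.8%, 84.7% and 85.9% of genes in NG, HG and L5.

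Coverage divided by FPKM was the same within 1% for 88.6%, 90.2% and 90.0% of transcripts of NG, HG and L5, and with 200 bases per fragment gave the fragments per library. The tables list 58984 gene IDs and 201289 transcripts in all 3 libraries, including 92 spike-in sequences, of which 83, 88 and 90 were detected. The spike-ins were left out of the gene counts, as were 28 features listed in the L5 table alone, features whose status was not OK, and genes whose longest isoform was under 300 nt. XIST and genes on chromosome Y were not named. On alternate contigs, 2385 gene IDs were kept. Mitochondrial genes without ribosomal RNA held 6.45%, 7.21% and 6.73% of fragments.

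For each pair of libraries the background was every gene with status OK in both and at least 1 FPKM in at least 1. The size rule asks for a log2 ratio of FPKM with a pseudocount of 1 of at least 1 in size. No test across samples exists with 1 library per group, so passing the size rule describes these libraries. Counting standard errors were taken from the deposited intervals, rescaled to centre on the listed FPKM, or from the upper arm where the lower bound was 0. The rule of separate intervals used the bounds as deposited, also where they did not hold the FPKM. Named genes were fixed by rule before the data were examined: in each of HG against NG and L5 against HG the 12 highest and 12 lowest ratios past the size rule with at least 5 FPKM in 1 library, separate intervals and an approved-style symbol; the 10 highest and 10 lowest in both comparisons with NG; per gene list up to 4 members past the size rule with at least 5 FPKM, or else the 2 largest; each glucose-sensing gene at 5 FPKM or more; and MAN2A2 and CHD8. Some genes that the rule names are not reported.

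The 27 gene lists were also fixed beforehand, with 3 further marker lists for hepatocytes, fibroblasts, and leukocytes and endothelium. The CD24 and PECAM1 symbols were not found. A list's median was placed among 10000 random lists of the same size drawn from the same 20 expression bins. Of 81 medians, 39 lay outside the middle 95%. By chance 4 would if genes varied independently, which the members of a list need not. The percentiles describe these libraries and are no test of a condition. In 5 cases median and mean differed in sign, none of them outside the middle 95%. Isoform shares are parts of a gene's summed isoform FPKM in genes at 10 FPKM or more; beside a fixed set of genes, the rule allowed the 8 largest changes per comparison to be named, of which those past 40 points are given. Shared genes were compared with 100 simulated sets of unchanged libraries.

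The steps were tested on simulated data. Between HG and NG, 91.0% of genes with an implanted 3-fold change and 99.0% of those with a 6-fold change were recovered, and 10 of 12917 unchanged genes passed. Between L5 and HG these were 82.0%, 99.0% and 3 of 12909. All 50 shifted lists were found in each, and so was an implanted stretch of 60 shifted neighbouring genes. With genes in shuffled order and no implanted shift, 1 false stretch was found between HG and NG and 0 between L5 and HG, against the extremes of 20 random orders in place of the 100 used for the data. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, other filters, median, upper quartile and TPM scaling, separate intervals and isoform sums. Alternatives chosen after seeing the data were spike-in scaling, removal of a length and GC trend (GC was known for 94.3% of the background of HG against NG), sums over gene IDs with the same symbol, main chromosomes alone, and leaving out genes in shifted chromosome stretches. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.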

Results

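KKU-213 is an established human cell line from an intrahepatic cholangiocarcinoma, a cancer of the bile ducts inside the liver. Poly-A RNA was sequenced from KKU-213 kept in medium with 5.6 mM glucose (NG), from KKU-213 kept in 25 mM glucose (HG), and from KKU-213L5 kept in 25 mM glucose (L5). The labels give more than 5 passages for each culture. KKU-213L5 is known as a highly metastatic subline of KKU-213. Each group had 1 library, so no difference between groups has a replicate check, and every comparison describes 3 libraries. The coverage columns put the libraries at 47.1 M fragments for NG, 76.0 M for HG and 68.7 M for L5. At least 1 FPKM was listed for 13286 genes in NG, 12884 in HG and 13041 in L5. All ratios are log2 ratios of FPKM + 1, which understate differences of genes listed near 0. Errors after ± are counting standard errors of the log2 ratio from the deposited intervals, and say nothing about the spread between cultures. Coordinates are on GRCh37, 1-based.

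Of 21 cholangiocyte markers, 8 reached 1 FPKM in NG and 10 in each of HG and L5. The highest, KRT7, a keratin of bile duct cells, was listed at 992 FPKM in NG, 784 in HG and 789 in L5. Of 21 hepatocyte markers, 2 reached 1 FPKM in NG and 1 in each of HG and L5, led by SERPINA1 at 77.8, 27.8 and 36.5 FPKM. Of 14 fibroblast markers, ACTA2 alone reached 1 FPKM, at 7.76 FPKM in NG, 2.82 in HG and 2.10 in L5. Of 15 leukocyte and endothelial markers, 1 reached 1 FPKM in NG and 2 in HG and L5, with CD68 highest at 12.5, 13.3 and 16.1 FPKM, and CD14 at 0.899, 3.15 and 1.83 FPKM.

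The series' design asks what medium glucose does to the transcriptome, and HG and NG differ in it by label. They were separate cultures of more than 5 passages, so a difference need not be a direct response to glucose. In HG, the calcium-binding proteins S100A14, S100A7, S100A8 and S100A9 and the squamous keratins KRT5, KRT6A and KRT14 were higher than in NG, while VIM and the VCX genes were lower. X-linked cancer-testis genes, a class normally active in the germ line that includes VCX, went both ways, with 6 of 18 higher and 10 lower. S100A8 was listed at 3.46 FPKM in NG and 162 in HG, and KRT5 at 1.71 and 43.3 FPKM. VIM was listed at 87.4 FPKM in NG and 8.55 in HG. Relative to all genes, the lists of the hypoxia response, glycolysis and cholesterol and fatty acid synthesis stood higher in HG, and those of the mesenchymal state, the matrix, interferon and the unfolded protein response lower.

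By the size rule, a log2 ratio of FPKM + 1 of at least 1 in size, 561 of 13383 genes differed between HG and NG. Of these, 176 were higher and 385 lower in HG, a higher share of 31.4%. A size of 4-fold was reached by 27 higher and 40 lower genes. The median log2 ratio of all genes was -0.09. Scaled to spike-in RNA, an alternative added after seeing the data, the all-gene median was -0.51, with 92 genes higher and 1307 lower. Under that scaling the glycolysis (-0.27), fatty acid (-0.22), cholesterol (-0.12), mitochondrially encoded (-0.38) and heat shock (-0.32) lists had medians below 0 and above that all-gene median.

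The highest ratios were those of S100A14 (ENSG00000189334, chromosome 1, 153586731 to 153589462), at 1.46 FPKM in NG and 115 in HG (log2 ratio 5.55 ± 0.16). S100A7 stood at 5.34 ± 0.28, S100A8 (ENSG00000143546, chromosome 1, 153362508 to 153363664) at 5.19 ± 0.17 and S100A9 at 4.20 ± 0.13. S100A8 and S100A9 form calprotectin, a protein of inflamed epithelium and neutrophils. KRT5 (ENSG00000186081, chromosome 12, 52908359 to 52914471) had a log2 ratio of 4.03 ± 0.11. KRT6A stood at 3.37 ± 0.13 and KRT14, the usual partner of KRT5 in basal epithelial cells, at 2.80 ± 0.13. CA2, a carbonic anhydrase, was listed at 0.102 FPKM in NG and 13.2 in HG. The cancer-testis genes MAGEA12 and CSAG1 had log2 ratios of 3.55 and 3.08. A short second gene ID with the symbol PA2G4 (ENSG00000257411) was listed at 25.2 FPKM in HG and 0.000861 in NG, a ratio of 4.71 ± 0.15 that ranked between S100A8 and S100A9. That value is uncertain, because the main PA2G4 gene it shares reads with was listed at 253 and 264 FPKM.

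Among the 12 lowest ratios were 4 genes of the VCX family on the X chromosome, with VCX3B (ENSG00000205642, chromosome X, 8432871 to 8434550) at 25.3 FPKM in NG and 0.408 in HG (log2 ratio -4.22 ± 0.11). VCX, VCX3A and VCX2 had log2 ratios of -4.04, -3.96 and -2.77; these near-identical copies share reads, so the split among them is uncertain. The cancer-testis genes GAGE2A, also one of several close copies, and SSX1 had ratios of -3.19 and -2.69. ANXA6, an annexin, was listed at 53.5 FPKM in NG and 2.5 in HG, and ACTL8 at 35.2 and 1.85 FPKM. VIM (ENSG00000026025, chromosome 10, 17270258 to 17279592), the intermediate filament of mesenchymal cells, had a log2 ratio of -3.21 ± 0.05. CLDN11 stood at -2.95, SOHLH2, a transcription factor of germ cells, at -2.80 and PODXL, a sialomucin of the cell surface, at -2.58.

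**Figure D1:**
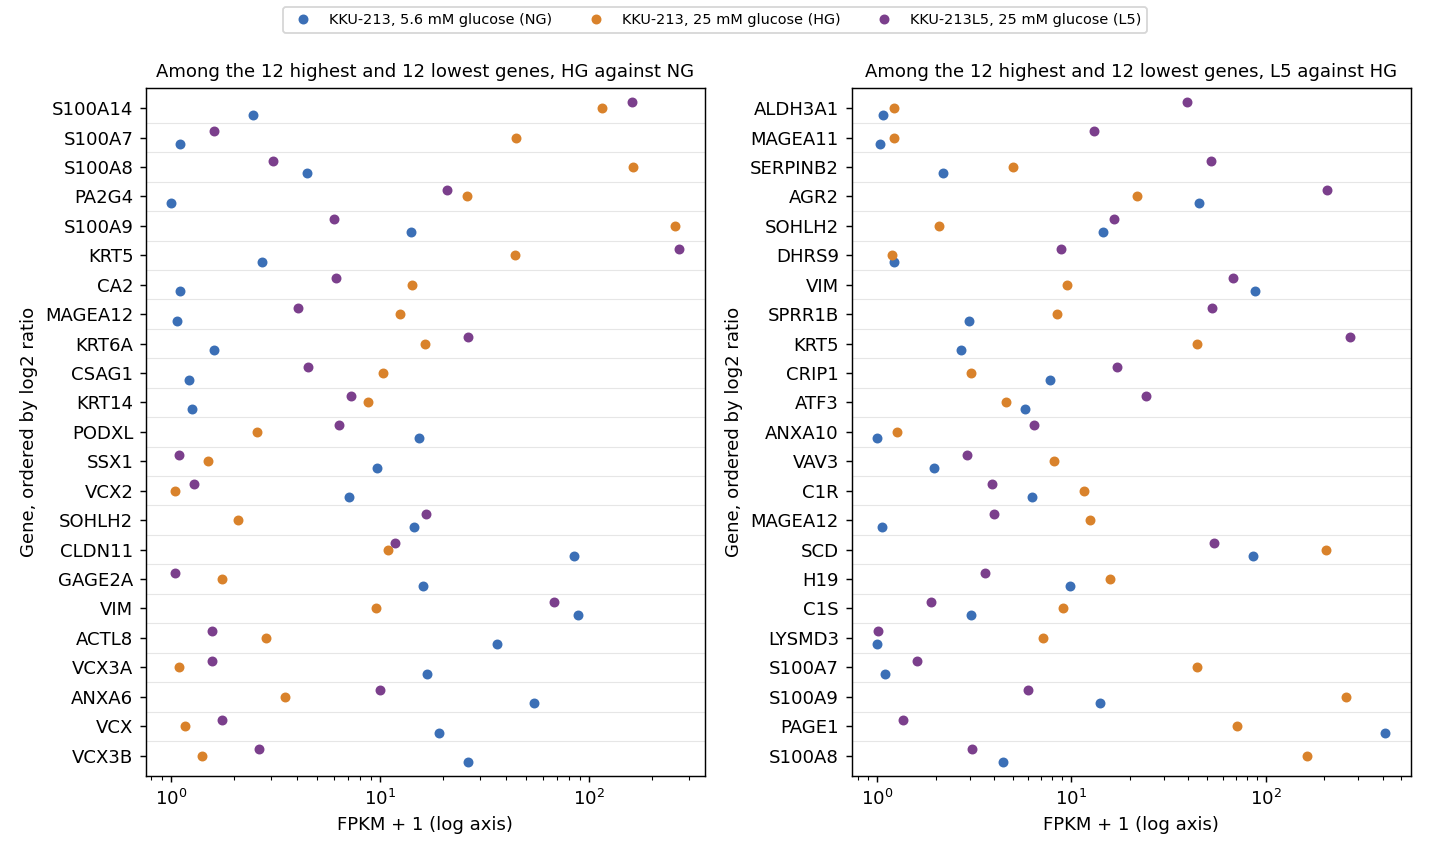
FPKM + 1 on a log axis in the 3 libraries (blue NG, orange HG, purple L5) for genes among the 12 highest and 12 lowest of HG against NG (left) and of L5 against HG (right); each point is 1 library and no error is drawn. S100A8 lay at 3.46 FPKM in NG, 162 in HG and 2.07 in L5, while KRT5 was highest in L5 at 270 FPKM; PA2G4 and LYSMD3 are second gene IDs of these symbols.

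Of 27 gene lists with at least 3 measured members, 12 had a median outside the middle 95% of matched random lists in HG against NG. The hypoxia response list had a median log2 ratio of 0.44 (percentile 100.0 of 10000 random lists). Of its 17 measured genes, 4 were higher by the size rule and none lower, among them NDRG1 (1.46 ± 0.10), EGLN3 (1.13 ± 0.08), an oxygen-sensing hydroxylase, and DDIT4 (1.10 ± 0.03). The cholesterol list had a median of 0.33 (percentile 100.0), with 2 of 23 genes past the size rule, both higher. The fatty acid synthesis list had a median of 0.24 (percentile 99.96), or 0.11 without genes in shifted chromosome stretches and 0.15 with a length and GC trend removed. SCD, which makes monounsaturated fatty acids, was the 1 of its 14 genes past the size rule, at 85.0 FPKM in NG and 204 in HG. The glycolysis and lactate export list had a median of 0.20 (percentile 99.98), but none of its 22 measured genes was higher by the size rule and 1 was lower. That gene was the glucose transporter SLC2A3 (2.46 and 0.424 FPKM); it and LDHA, at 1372 and 1634 FPKM, were chosen for mention after their values were seen. The heat shock list (0.14, or 0.22 with the length and GC trend removed) and the mitochondrially encoded proteins (0.09, or 0.14) were the remaining lists above the random range, with no gene past the size rule. HSF1 stood at 0.41 and HSPE1 at -0.63, and MT-CO1 at 0.35 and MT-ND6 at -0.52. The heat shock median was -0.07 once genes in shifted chromosome stretches were left out.

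The mesenchymal list had the lowest median in HG, -0.68 (percentile 0.03), with 4 of 9 measured genes lower by the size rule; the median was -1.61 over genes at 5 FPKM or more and -0.08 with no filter on FPKM. These were VIM, S100A4 (-1.77 ± 0.08), TGFBI (-1.61 ± 0.04) and ACTA2 (-1.20 ± 0.11). The unfolded protein response list, chaperones and related genes of the endoplasmic reticulum, had a median of -0.48 (percentile 0.01) with all 18 genes inside the size rule; MANF was listed at 160 FPKM in NG and 80.5 in HG, and PDIA4 at 77.5 and 42.0. The matrix list had a median of -0.46 (percentile 0.0), with 4 genes higher and 3 lower of 26, or -0.16 with no filter on FPKM. The lower ones were CTSL1 (-1.28), TIMP2 (-1.25) and ITGB6 (-1.10). The 4 higher ones were the metalloproteinases MMP1, MMP3, MMP10 and MMP13, named after their values were seen, all at 3.11 FPKM or less in HG. The interferon list had a median of -0.44 (percentile 0.0), with 5 of 26 genes lower, among them IFI44 (-1.95 ± 0.07), OASL (-1.31 ± 0.09), OAS1 (-1.28 ± 0.13) and IFIT1 (-1.09 ± 0.07). The NF-kB and cytokine list had a median of -0.28 (percentile 2.16), or -0.54 without genes in shifted chromosome stretches, with 5 lower and 2 higher of 20. Its chemokines CXCL5, CCL20 and CXCL1 stood at -1.82, -1.45 and -1.40, while IL1B was higher at 60.5 FPKM in NG and 164 in HG (1.42 ± 0.03). Nuclear genes of oxidative phosphorylation had a median of -0.25 (percentile 0.76), with all 30 inside the size rule; COX6C and NDUFB8 stood at -0.48 and -0.52. With a length and GC trend removed, a setting chosen after seeing the data, that list lay inside the random range (percentile 2.56).

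The list of glucose-sensing targets and that of the hexosamine pathway and N-glycan maturation lay inside the random range. Targets of MondoA and ChREBP, the transcription factors that sense glucose metabolites, had a median log2 ratio of -0.18 (percentile 24.39) over 8 measured genes, none past the size rule. TXNIP, their best known target, was listed at 11.3 FPKM in NG and 11.3 in HG (0.01 ± 0.06). KLF10 stood at -0.60, DAK at 0.62, KLF11 at -0.31 and BHLHE40 at -0.04. The hexosamine and N-glycan list had a median of -0.20, with MAN1A1 its 1 gene past the size rule at 1.65 ± 0.06; MAN1A1 lies on chromosome 6, whose genes stood higher together in HG. MAN2A2, a mannosidase of N-glycan maturation, and the chromatin remodeller CHD8 were fixed for reporting beforehand. MAN2A2 was listed at 3.20 FPKM in NG and 2.73 in HG (-0.17 ± 0.20), and CHD8 at 19.4 and 19.0 FPKM (-0.03 ± 0.11), differences smaller than their counting error.

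The other lists inside the random range in HG against NG had these medians. The pentose phosphate pathway stood at -0.07 (H6PD 0.36, RPIA -0.55), antioxidant and NRF2 targets at -0.13 (SOD2 0.87, FTL -0.78) and STAT3 signalling at -0.01. In the STAT3 list 2 of 23 genes were lower, LCN2 at -2.03 ± 0.05 and IL6 at -1.49 ± 0.12. Epithelial junction genes stood at 0.06, or above the random range at 0.09 (percentile 98.54) with the length and GC trend removed, with 2 of 22 higher, the junction proteins CLDN1 (1.26 ± 0.02) and DSP (1.10 ± 0.02). S phase genes stood at -0.05 (E2F1 -0.61, UHRF1 -0.42), G2 and mitosis genes at -0.17 (AURKB -0.51, BUB1B -0.42) and p53 targets at -0.16 (GDF15 0.79, PMAIP1 -0.65). The Wnt list stood at -0.13, with LEF1 lower at -1.08 ± 0.16 and RNF43 higher at 1.45 ± 0.17. Cholangiocyte markers stood at -0.23, with PROM1 (-1.36) and SOX9 (-1.06) lower and GGT1 higher at 1.13 ± 0.17; RNF43 and GGT1 were chosen after their values were seen. Cytosolic ribosomal proteins stood at -0.19 (RPS3 -0.64, RPL11 -0.61), immediate early genes at -0.20, with the phosphatase gene DUSP4 lower at -1.42, and replication-dependent histones at 0.01 (HIST1H4C 0.69, HIST1H1E 0.59). Without genes in shifted chromosome stretches, the immediate early median was 0.0 and the histone median -0.30, the latter over 3 genes. In the ATF4 list, at 0.01, the amino acid transporter SLC7A5 was higher at 1.16 ± 0.01.

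**Figure D2:**
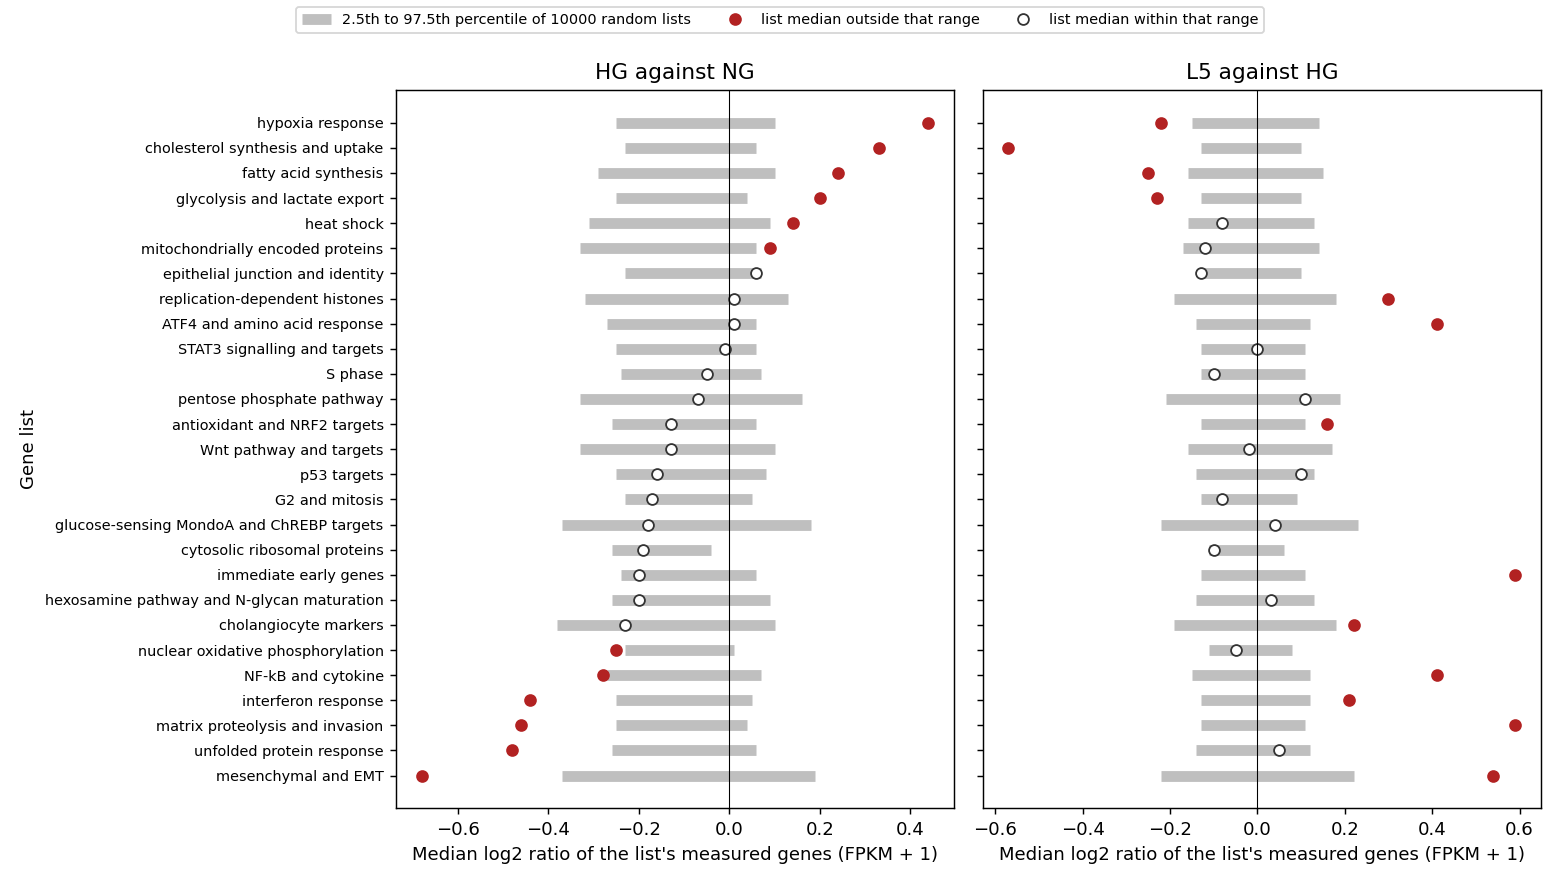
Median log2 ratio (FPKM + 1) of each gene list for HG against NG (left) and L5 against HG (right); grey bars span the middle 95% of 10000 random lists matched on expression, and filled points lie outside them. The mesenchymal list lay at -0.68 on the left and 0.54 on the right, and the cholesterol list at 0.33, or -0.12 against an all-gene median of -0.51 when scaled to spike-in RNA, and -0.57.

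L5 and HG shared the labelled glucose of 25 mM, so their comparison sets the metastatic subline against KKU-213. Relative to all genes, L5 had higher VIM and higher lists of immediate early genes, NF-kB and cytokine genes and ATF4 targets than HG, and lower S100A8, S100A9, S100A7 and genes of cholesterol and fatty acid synthesis. VIM was listed at 8.55 FPKM in HG and 67.0 in L5, and S100A9 at 257 and 5.01 FPKM. NG, also KKU-213, had 87.4 FPKM for VIM and 13.05 for S100A9, nearer to L5 than to HG. A deviation of the HG library alone would give such differences. The ATF4 (0.59) and immediate early (0.40) lists were higher in L5 than in NG too. KRT5, already higher in HG than in NG, stood higher still in L5 at 270 FPKM.

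By the size rule, 293 of 13129 genes differed between L5 and HG, 226 higher and 67 lower in L5 (77.1% higher), with a median log2 ratio of all genes of -0.01. Scaled to spike-in RNA, 89 were higher and 231 lower, with an all-gene median of -0.36. Under that scaling the antioxidant (-0.22), NF-kB (-0.01), ATF4 (-0.01), interferon (-0.13), cholangiocyte (-0.19) and histone (-0.09) lists had medians below 0 and above that all-gene median. The highest ratio was that of ALDH3A1 (ENSG00000108602, chromosome 17, 19641297 to 19652256), an aldehyde dehydrogenase, at 0.221 FPKM in HG and 38.3 in L5 (5.01 ± 0.09). MAGEA11 was listed at 0.219 and 12.1 FPKM (3.42 ± 0.07), and SERPINB2, an inhibitor of urokinase, at 4.03 and 51.4 FPKM (3.38 ± 0.07). AGR2, a protein disulfide isomerase of secretory epithelium, was listed at 20.8 and 206 FPKM (3.24 ± 0.06). SOHLH2 (3.0), DHRS9 (2.89), VIM (2.83 ± 0.06), SPRR1B, a squamous envelope protein (2.66), and KRT5 (2.61 ± 0.04) followed. CRIP1, ATF3 and ANXA10 had ratios of 2.49, 2.39 and 2.34.

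S100A8 had the lowest ratio, -5.73 ± 0.15, at 2.07 FPKM in L5. PAGE1 (ENSG00000068985, chromosome X, 49452053 to 49460596), a cancer-testis gene, was listed at 411 FPKM in NG, 70.4 in HG and 0.356 in L5, a ratio of -5.72 ± 0.12 between L5 and HG. S100A9 stood at -5.43 and S100A7 at -4.80. The complement proteases C1S and C1R stood at -2.25 and -1.58, the imprinted RNA H19 at -2.13, SCD at -1.92, MAGEA12 at -1.63 and VAV3 at -1.48. A second gene ID with the symbol LYSMD3 (ENSG00000259141) was listed at 6.13 FPKM in HG and 0.00671 in L5; the value is uncertain, because the main LYSMD3 gene it shares reads with was at 8.44 and 11.8 FPKM.

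In L5 against HG, 13 of the 27 lists lay outside the random range. Immediate early genes, the fast targets of growth factor signalling, had a median of 0.59 (percentile 100.0), with 5 of 22 genes higher, among them ATF3, FOSB (1.49 ± 0.04), DUSP4 (1.35 ± 0.03) and KLF6 (1.33 ± 0.04). The matrix list stood at 0.59 (percentile 100.0), with CTSL1 (1.41 ± 0.05) and LAMA3 (1.33 ± 0.02) the 2 of 25 past the size rule; the median was 0.36 with a pseudocount of 5 and 0.32 with no filter on FPKM. The mesenchymal list stood at 0.54 (percentile 99.99), where VIM was the 1 of 8 genes past the size rule; the median was 0.03 with no filter on FPKM. The NF-kB and cytokine list stood at 0.41 (percentile 100.0), or 0.25 without genes in shifted chromosome stretches, with 5 of 19 higher, among them IL8 (1.63 ± 0.05), CXCL3 (1.57 ± 0.11), CCL20 (1.32 ± 0.08) and TNFAIP3 (1.06 ± 0.05). The ATF4 list stood at 0.41 (percentile 100.0), with 4 of 19 higher, including ATF3, PPP1R15A (1.38 ± 0.04) and the cystine transporter SLC7A11 (1.30 ± 0.03). Antioxidant and NRF2 targets stood at 0.16 (percentile 99.66), or 0.37 without genes in shifted chromosome stretches, with AKR1C2 (1.22), SLC7A11 and GPX2 (1.05) higher and SOD2 lower at -1.06 ± 0.04; SOD2 lies on chromosome 6, whose genes stood lower together in L5. The interferon list stood at 0.21 (percentile 99.94), with IFI44 higher at 1.21 ± 0.07. Histones stood at 0.30 (percentile 99.74), although HIST1H4C, the 1 of 11 past the size rule, was lower at -1.37 ± 0.10. Most measured histones lie on chromosome 6, and without genes in shifted chromosome stretches too few were left for a median. Cholangiocyte markers stood at 0.22 (percentile 98.66), or 0.01 with no filter on FPKM, with none of 10 past the size rule. SOX9 stood at 0.94 and KRT18 at 0.33. Without genes in shifted chromosome stretches that list lay inside the random range.

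The cholesterol list had the lowest median in L5 against HG, -0.57 (percentile 0.0), with 1 of 23 genes lower by the size rule. Fatty acid synthesis stood at -0.25 (percentile 0.43), or -0.15 without genes in shifted chromosome stretches, with 2 of 13 genes lower, SCD and FASN (-1.02 ± 0.06). Glycolysis stood at -0.23 (percentile 0.02), with all 21 genes inside the size rule, ALDOC (-0.90) and SLC16A1 (-0.53) showing the largest ratios. The hypoxia response stood at -0.22 (percentile 0.25), with DDIT4 (-1.18 ± 0.03) and EGLN3 (-1.02 ± 0.08) the 2 of 17 lower. These 4 lists were among those that stood higher in HG than in NG, and both comparisons use the HG library, so a deviation of that library alone would put opposite signs on them. The same applies to the mesenchymal, matrix, interferon and NF-kB lists, which stood lower in HG than in NG. Their medians were -0.68, -0.46, -0.44 and -0.28 there, and 0.54, 0.59, 0.21 and 0.41 in L5 against HG.

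The remaining lists of L5 against HG lay inside the random range with all genes used. Their medians were 0.04 for MondoA and ChREBP targets (TXNIP 0.46, BHLHE40 -0.43), 0.11 for the pentose phosphate pathway (TKT -0.31) and 0.03 for the hexosamine list, where MAN1A1 was lower at -1.43 ± 0.05 and GFPT2, chosen after its values were seen, higher at 1.33 ± 0.17. Mitochondrially encoded proteins stood at -0.12 (MT-ND6 0.74, MT-ND1 -0.22), nuclear oxidative phosphorylation at -0.05 (CYC1 -0.35, NDUFS3 -0.27), epithelial junctions at -0.13 (CDH1 0.53, ELF3 -0.44) and STAT3 signalling at 0.0 (SAA1 -0.98, SAA2 -0.82). The unfolded protein response stood at 0.05 (HERPUD1 0.50, MANF -0.46), S phase at -0.10 (MCM3 -0.47, MCM2 -0.27), G2 and mitosis at -0.08 (HMMR -0.31, BUB1B 0.26) and p53 targets at 0.10 (TP53I3 0.66, PMAIP1 0.58). The Wnt list stood at -0.02 with a mean of 0.10 (WNT7B 0.71, CTNNB1 -0.69), but at 0.21 (percentile 97.66), above the random range, without genes in shifted chromosome stretches. Ribosomal proteins stood at -0.10 (RPS12 -0.66, RPL15 -0.49) and heat shock at -0.08 (HSPA1B -0.68, HSPA1A -0.66, near-identical copies that share reads). The HSPA1A and HSPA1B IDs used lie on alternate contigs of chromosome 6, whose genes stood lower together in L5. They are not counted among the named genes in shifted stretches. MAN2A2 was at 2.37 FPKM in L5 (-0.15 ± 0.16 against HG) and CHD8 at 18.8 FPKM (-0.02 ± 0.09).

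Against NG, L5 differed in both cell population and labelled glucose. KRT5 (6.64 ± 0.10) and S100A14 (6.03 ± 0.16) stood far higher in L5, and the cancer-testis gene PAGE1 far lower (-8.25 ± 0.11). VIM, unlike in HG, was close to NG (-0.38 ± 0.03). By the size rule, 528 of 13474 genes differed, 254 higher and 274 lower in L5 (48.1% higher). The majority turned under the scalings planned beforehand, with 301 higher and 231 lower by median, 283 and 242 by upper quartile and 397 and 310 by TPM. Scaled to spike-in RNA the split was 83 higher and 4522 lower, with an all-gene median of -0.86 in place of -0.10. The ATF4 list had a median of 0.59 with 6 of 19 genes higher, and immediate early genes stood at 0.40 with 3 of 22 higher. The unfolded protein response (-0.46), the mesenchymal list (-0.38), ribosomal proteins (-0.32), the interferon list (-0.31), G2 and mitosis (-0.28) and nuclear oxidative phosphorylation (-0.28) lay below the random range. Hypoxia (0.20, or 0.10 without genes in shifted chromosome stretches), histones (0.22), the matrix list (0.14), antioxidant targets (0.11, or 0.21 without them), the NF-kB list (0.08) and epithelial junctions (0.06) lay above it. Without genes in shifted chromosome stretches, histones, the NF-kB list and epithelial junctions lay inside it. The cholesterol (-0.22), fatty acid (-0.17) and glycolysis (-0.01) lists lay inside it. List medians of this comparison were not recomputed under other scalings. MAN2A2 stood at -0.32 ± 0.20 and CHD8 at -0.05 ± 0.11.

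Genes that stood apart from NG in both libraries grown at 25 mM glucose were led by keratins and S100A14 on the higher side and by cancer-testis genes on the lower side. S100A14 was listed at 1.46 FPKM in NG, 115 in HG and 160 in L5, and KRT6A at 0.593, 15.4 and 25.5 FPKM. KRT5, KRT14, CA2, TRIM29 (1.91, 16.9 and 12.5 FPKM), MGA (0.218, 6.38 and 5.95 FPKM) and C12orf54 were also among the 10 highest, with the uncertain PA2G4 ID. MGA lies in a stretch of chromosome 15 whose genes stood higher together in HG. PAGE1, ACTL8, CLDN11, ANXA6, SSX1, GAGE2A and the 4 VCX genes were the 10 lowest.

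Of 13238 genes measured in both comparisons with NG, 81 were higher and 160 lower in both. Lists of these sizes drawn independently would share 2.2 and 7.9 genes. Unchanged libraries were simulated with counting error around each gene's mean over the 3 libraries, and both comparisons shared the simulated NG library. They gave 2.37 and 0.63 shared genes, and 4.52 and 4.05 with the spread of the spike-ins added as random noise per gene. The covariance of the log2 ratios was 0.147, against 0.010 and 0.078 in those simulations, leaving 0.137 and 0.069. With 1 NG library the controls cannot be split, so what that library contributes to the overlap was not separated.

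For 378 of the 560 genes that differed between HG and NG and had a usable L5 value (67.5%), L5 lay nearer to HG than to NG. VIM, SOHLH2, S100A8, S100A9 and S100A7 were among those nearer to NG. Of 12899 genes measured in HG against NG and in L5 against HG, 32 were higher in HG and lower again in L5, and 66 were lower in HG and higher again in L5. Independent lists would share 0.9 and 3.9 genes, and simulated unchanged libraries with counting error shared 0.32 and 0.53. Both comparisons use the HG library, with opposite signs, so a deviation of that library alone would give such genes. The simulated libraries hold no spread between cultures, so they cannot decide on such a deviation.

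Isoform shares, each isoform's part of its gene's summed FPKM, differed little for most genes. Of 5643 genes with several isoforms and at least 10 FPKM in HG and NG, 58 had an isoform whose share differed by at least 20 percentage points, and 1 by at least 40. That gene was EPDR1, where ENST00000199448 held 86.6% in NG, 0.3% in HG and 35.5% in L5. Between L5 and HG, 53 of 5632 genes reached 20 points and 3 reached 40. These 3 were ATAD3A (ENST00000536055, 0.5% in HG and 51.3% in L5), PCDH1 (ENST00000394536, 18.0% and 63.3%) and CD82 (ENST00000227155, 32.8% and 76.5%). PKM, the pyruvate kinase of glycolysis, had 64.0%, 71.6% and 69.4% of its FPKM on ENST00000335181 in NG, HG and L5. For TPM1, ENST00000358278 held 5.8%, 20.7% and 20.4%. The largest share changes between HG and NG in CD44, CTNND1, ENAH, FGFR2 and MKNK2 were -4.1, -4.6, 1.5, -0.2 and 1.5 points, in VEGFA -5.5 and in BCL2L1 11.6. Cufflinks estimates isoforms from reads they share, and no interval was computed for these shares.

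Neighbouring genes differed together over long stretches of chromosomes. Medians of log2 ratios over windows of 40 genes at 3 FPKM or more lay beyond the extremes of 100 random gene orders in 8 stretches between HG and NG and in 6 between L5 and HG. On chromosome 6 the 421 genes stood higher in HG than in NG by a median of 0.37, with 88.1% of them above the genome-wide median, and the 422 genes lower in L5 than in HG by -0.34. L5 lay close to NG there (0.06), as it did for the stretch of chromosome 9 given below (-0.02), so HG alone stood apart and both shifts rest on that library. On chromosome 3, from 3.2 to 160.2 Mb, 457 genes stood lower in L5 than in HG by a median of -0.34. Other stretches higher in HG than in NG lay on chromosomes 1 (45.5 to 145.5 Mb, 0.40), 2 (101.6 to 170.7 Mb, 0.30) and 15 (34.7 to 75.4 Mb, 0.36), and a stretch of chromosome 9 (125.1 to 140.8 Mb) was lower at -0.33. In L5 against NG the stretches of chromosomes 1, 2 and 15 stood at 0.32, 0.23 and 0.44, so HG and L5 both stood above NG there. From 94.3 to 145.6 Mb on chromosome 1, however, L5 stood lower than HG by -0.29 and at 0.11 against NG. In L5 against HG, most of chromosome 9 (35.7 to 140.8 Mb) stood higher at 0.31. The shifts were small beside the size rule. Of genes at 3 FPKM or more in both libraries, 32 past it between HG and NG, and 11 between L5 and HG, lay in a stretch with the same direction. With genes of any level inside any stretch left out, 435 of 10450 genes passed it between HG and NG, in place of 561 of 13383. Between L5 and HG these were 237 of 10237, in place of 293 of 13129. Of the 138 genes named by rule, 35 lay in a stretch by position, whatever their own direction. IFI44 (-1.95) and ITGB6 (-1.10), for example, were lower in HG than in NG inside stretches that stood higher. The 35 included IFI44, TXNIP, SLC16A1 and VAV3 on chromosome 1, IL1B, ITGB6 and DHRS9 on chromosome 2, and LCN2 and CTSL1 on chromosome 9. DSP, SOD2, MAN1A1, TNFAIP3, MCM3, RPS12, HIST1H4C and HIST1H1E lay on chromosome 6, CLDN1, CLDN11, MANF, TKT, MCM2, CTNNB1, RPL15 and BHLHE40 on chromosome 3, MGA and BUB1B on 15, and ALDH3A1, ALDOC, SOX9 and TIMP2 on 17.

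**Figure D3:**
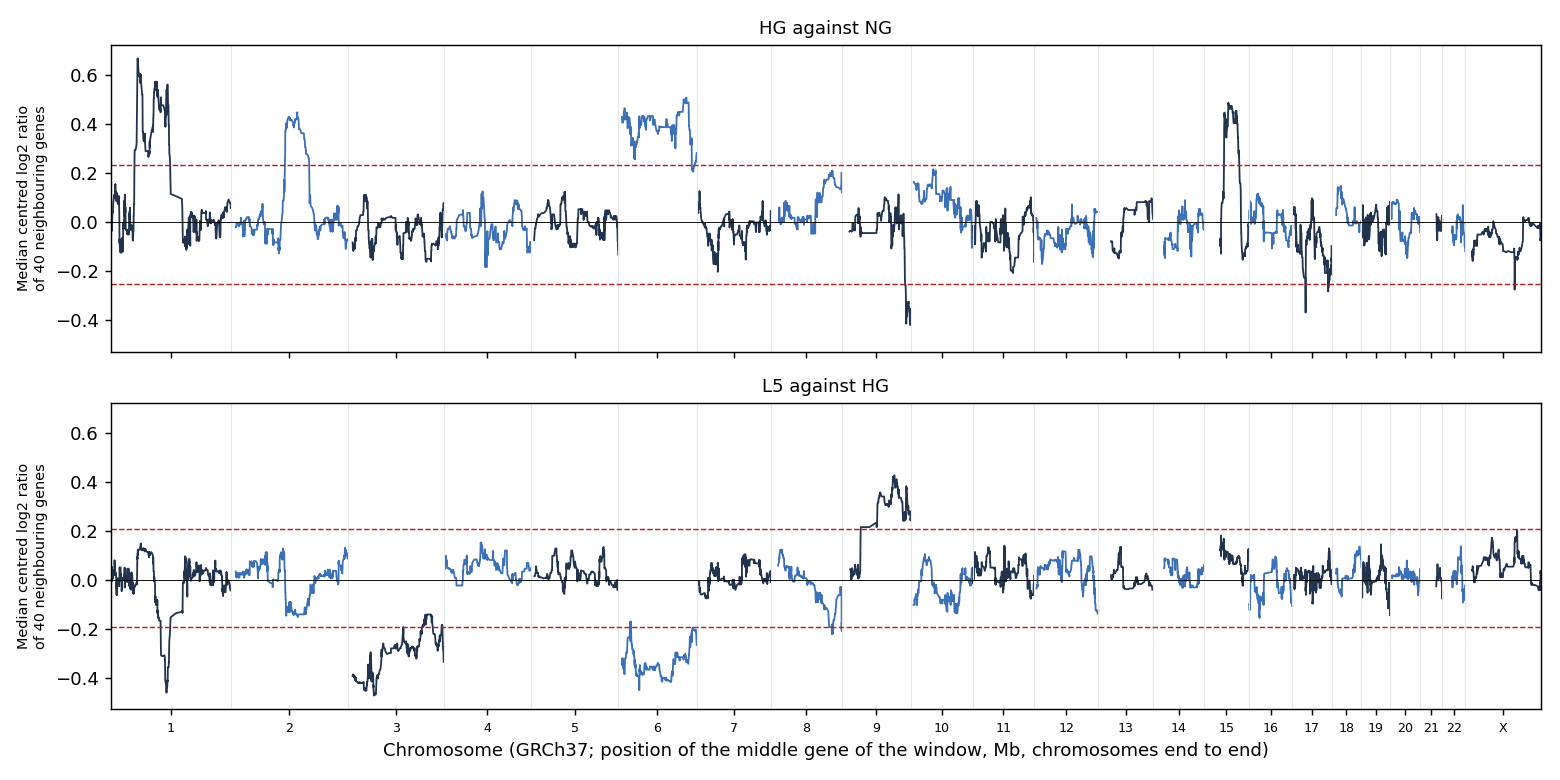
Centred median log2 ratio of windows of 40 neighbouring genes along the chromosomes (GRCh37) for HG against NG (top) and L5 against HG (bottom); colours alternate by chromosome and dashed lines are the extremes of 100 random gene orders. Chromosome 6 lay at 0.37 in HG against NG and at -0.34 in L5 against HG.

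**Figure D4:**
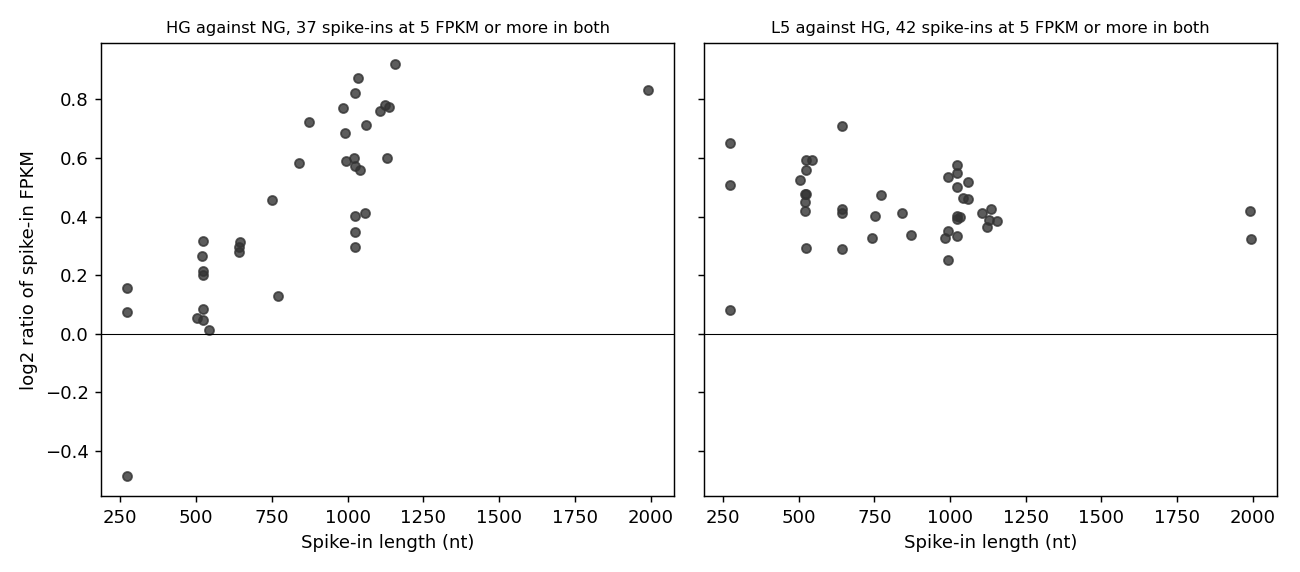
Log2 ratio of each spike-in sequence against its length in nt, for HG against NG (left) and L5 against HG (right); each point is 1 spike-in at 5 FPKM or more in both. Between HG and NG the median was 0.179 for the shorter and 0.599 for the longer spike-ins.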

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

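The tests of the spike-ins were chosen after their ratios had been seen. Spike-in sequences, which the labels do not mention and the comparisons above do not use, held 1.841% of assigned fragments in NG, 2.541% in HG and 3.516% in L5, a signal above 0 in every library. The median log2 ratio was 0.413 for 37 spike-ins between HG and NG and 0.419 for 42 between L5 and HG. Length-dependent recovery in the NG library may account for part of the first step, since across spike-ins Spearman's rho of length and ratio was 0.828 and Pearson's r with log2 length 0.831, or 0.793 without the 2 farthest; spike-ins are not independent replicates. It does not account for the rise from HG to L5, where all 42 ratios were above 0 with a median of 0.419 and rho was -0.243. A difference in RNA per cell or in the amount of spike-in added stays open, since the amounts are not in the labels.

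The L5 table alone listed 28 features, of which 18 were at 1 FPKM or more, led by SELENOF at 315, SEPTIN7 at 124 and SEPTIN2 at 116 FPKM. The NG and HG tables do not list these IDs at all, not even at 0, so they say nothing about a difference between the libraries; the 28 are genes once named SEPT, SEP15, MARCH, MARC or DEC1, names that spreadsheets read as dates.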

How the results depend on the processing

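Spike-in scaling and the settings on trend, symbols, contigs and chromosome stretches were chosen after seeing the data. A list median is said to have moved if it changed by more than the distance from the middle of its random range to its end. A named gene's ratio moved if it changed by more than 2 counting standard errors. Counts of genes past the size rule are given for HG against NG, L5 against HG, L5 against NG and shared by HG and L5 against NG. A pseudocount of 0.1 gave 1101, 569, 1024 and 533 genes and a pseudocount of 5 gave 150, 75, 152 and 70, which follows from its construction. At least 1 FPKM in both libraries left 334, 171, 296 and 123, and a filter of 5 FPKM left 316, 170, 289 and 135, since fewer genes were compared. Spike-in scaling gave 1399, 320, 4605 and 1059; the higher share went from 31.4% to 6.6% in HG against NG, from 77.1% to 27.8% in L5 against HG and from 48.1% to 1.8% in L5 against NG. Under the scalings planned beforehand the higher share in L5 against NG went to 56.6% (median), 53.9% (upper quartile) and 56.2% (TPM). All 4 counts stayed within 1.5 times their value under the other settings run. Under spike-in scaling, medians turned negative in HG against NG for glycolysis (-0.27), fatty acid synthesis (-0.22), cholesterol (-0.12), mitochondrially encoded proteins (-0.38) and heat shock (-0.32), and in L5 against HG for antioxidant targets (-0.22), NF-kB (-0.01), ATF4 (-0.01), interferon (-0.13), cholangiocyte markers (-0.19) and histones (-0.09), as the factor lowers every gene alike; the other 43 list medians moved. Heat shock turned to -0.07 without genes in shifted stretches; the cause was not tested. Other list medians that moved were, in HG against NG, mesenchymal (-1.27 and -0.28 with pseudocounts of 0.1 and 5, -0.08 with no FPKM filter, -1.61 at 5 FPKM), matrix (-0.16 with no filter), NF-kB (-0.54 at 5 FPKM and without shifted stretches), immediate early genes (0.0 without them) and histones (-0.30 without them). In L5 against HG they were matrix (0.36 with a pseudocount of 5, 0.32 with no filter), mesenchymal (0.03 with no filter), cholangiocyte markers (0.01 with no filter) and, without shifted stretches, antioxidant targets (0.37), NF-kB (0.25) and Wnt (0.21), which turned from -0.02 and went from inside to above the random range (percentile 97.66). No named gene with a call changed sign, but of 266 values 234 moved under spike-in scaling, 132 with a pseudocount of 5, 81 under TPM, 72 with a pseudocount of 0.1, 33 under median and 28 under upper quartile scaling and 26 with the trend removed. With the length and GC trend removed, 37 of 39 list medians stayed outside the random range, while epithelial junctions in HG against NG rose above it, and without genes in shifted stretches 33 of 38 stayed; histones in L5 against HG then had too few genes for a median. Isoform shares moved for 9 of 47 when short or not OK isoforms were left out.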

Other observations

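The tests of a length and GC trend as the whole cause for named stretches, the test of glucose for chromosomes 6 and 9, the dilution test for the cancer-testis genes and the gene families below were chosen after the results had been seen. Among keratin genes, 5 of 13 were higher in HG than in NG and none lower, and 7 of 13 were higher in L5 than in NG, led in both by KRT5 (4.03 and 6.64). Of 14 S100A genes, 5 were higher and 1, S100A4, lower in HG than in NG, and 4 were lower in L5 than in HG. Of 18 X-linked cancer-testis genes, 6 were higher and 10 lower in HG than in NG, and of 17 measured in L5 and NG, 5 were higher and 11 lower; VCX and GAGE copies share reads.

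The stretches of neighbouring genes that differed together numbered 14. The median share of a stretch's genes on its side was 83.2%, against 67.5% in permuted windows. Stretches were found by window medians, which a few genes with large changes barely move, so this share cannot decide on such genes. A length or GC trend as the whole cause for chromosomes 3 and 6 is argued against by the 97.3% or more of the shift they kept without it. The test of a trend over all 14, planned beforehand, did not decide it: 85.7% still passed the permuted extremes, between its bounds. Of the others, 8 kept at least 88.9% of the shift, but were picked for still passing, so that share is no separate test. A trend stays open for them and for the 2 that no longer passed. These lay on 17 from 65.8 Mb (-0.24 ± 0.032 to -0.21 ± 0.032, bootstrap SE) and on X (-0.27 ± 0.078 to -0.19 ± 0.072). A copy number or clonal difference between the cultures may account for the pattern: in 100.0% of stretches both the lower and the higher expressed genes shifted, against 70.5% in permuted windows, and genes of 1 to 3 FPKM, not used to find them, lay on the same side in 100.0%, some by close to 0. The permuted windows hold 40 genes and the stretches 41 to 457, so the larger sets may account for part of the contrast with 70.5%. Glucose did not differ by label for the 6 stretches between L5 and HG. For chromosomes 6 and 9 between HG and NG, L5 against NG had at most 16.4% of the shifts. Both were picked after these L5 values had been seen, so that share is no separate test. L5 is also another cell population, which may carry shifts of its own there. The share therefore cannot decide on glucose, which stays open for all 8 stretches between HG and NG. DNA was not measured.

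The keratin, S100 and cancer-testis differences between NG and HG could come from medium glucose, a different cell population or another line mixed into HG. Mixing as a minority of the RNA would leave at least 50% of a gene's NG level. For the cancer-testis genes, an earlier test of their median (5.4%, bootstrap interval 0.9 to 65.6%) did not decide on it. Of 10 at 5 FPKM or more in NG, 8 (80%) fell below 50% by more than 2 SD, in 4 of 5 families. Dilution alone would not leave such values for those 8 genes. The family was picked after members had been seen among the lowest ratios, and VCX copies share reads. The 80%, against 1.6% of all genes at that level, is therefore no separate test. Mixing stays open for the family. For the higher genes mixing stays open too: 23 went from under 0.1 FPKM in NG to 1 FPKM or more in HG, between the bounds set beforehand, and 30 went the other way. For glucose, L5 lay nearer to HG for 67.5% of genes past the size rule, also between its bounds. With 1 library per group, glucose, a different population and mixing cannot be told apart.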
